A study of Mus musculus with 6 samples.

How the data were processed

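Cardiac apex tissue of C57BL/6 and db/db mice, collected at 21 weeks of age, was profiled on 6 Agilent arrays of an Arraystar circRNA design, with 3 arrays per group. Each array held RNA of a separate animal, since the labels state that a different donor was used each time. Per the labels' protocols, total RNA was digested with RNase R, an enzyme that degrades linear RNA and spares circles, then amplified with random primers and labelled with Cy3. Per the file headers, the arrays were read with Agilent Feature Extraction 11.0.1.1, and the probes were designed on the mouse build mm9. The submitters' processing notes also name limma, with no version or role.

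Each array's deposited file gives an intensity per spot. Per the file headers, the processed intensity had been background-subtracted and detrended within the array, and it was not normalized between arrays. The deposited files also carry other columns per spot, namely 0 or 1 flags for saturation, outliers and signal over background, and the type of control spot. The authors' deposited table of the series holds log2 values, as judged by setting each column against the scanner intensities of the same array. Its column medians lay between 7.50 and 7.53, and its ranks followed the unsubtracted median intensity (Spearman correlation at least 0.9998 across probes, which are not independent replicates). Quantile normalization of that intensity came close to it, with a median absolute difference of at most 0.04 on the log2 scale per array. The largest difference was 0.48, so the exact steps behind the table remain unknown and are not given in the sources used here. The table has no column outside the 6 samples.

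Every array had 15712 spots, of which 15176 were not control spots and stood for 14330 distinct probes. These comprised 14236 circRNA probes, and 94 probes with 10 spots each. The repeated probes were 50 Agilent mRNA probes, 14 probes named as circRNA controls, 15 probes with custom names and 15 probes named as negative controls. The circRNA probes carry Arraystar probe IDs, which the files do not pair with circRNA names, host genes, classes of origin or coordinates. A circRNA is therefore given here by its probe ID, with at most 2 IDs per direction. Of the mRNA probes, 44 were named through their RefSeq accessions with the gene table of GRCm38.p6, used for names only because the array's build differs, and 6 remained unnamed.

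Log2 processed intensities of the spots of a probe were averaged, with outlier spots left out, and the 75th percentile of each array over its non-control probes was subtracted. Probes were tested when they were well above background on at least 3 of the 6 arrays and had a value on every array. That left 14218 circRNA probes, after 15 were dropped for an outlier spot and 3 as dim. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term), and p was adjusted by Benjamini-Hochberg within each probe family, with a threshold of 0.05. The requirement of a value on every array, and the reading of the mRNA and other repeated probes, were added after the data were examined. Technical measures of the arrays were compared by exact permutation tests, for which 0.1 is the smallest two-sided p with 3 arrays against 3. The number of arrays limits the precision of every value.

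The groups, tests, filter, gene lists, most alternatives and the rule for named circRNAs were fixed before the data were examined. The rule took, per direction, the 12 circRNAs of largest change past the adjusted threshold. Where fewer passed, it took those of smallest unadjusted p whose db/db arrays all lay on one side of the C57BL/6 arrays. The same rule also named members of host gene lists, circRNAs of Lepr, a pair of circRNAs studied earlier in diabetic mouse heart and detection-limited circRNAs. The 15 host gene lists, the classes of circRNA origin and the earlier-studied circRNAs could not be matched to probes and are not analysed here. The lists were read on the mRNA probes in their place, where 3 lists had a member and 12 had none. The lists without a probe were sarcomere and cardiomyocyte cytoskeleton, calcium handling, extracellular matrix, fibroblast markers, leptin receptor signalling, mitochondrial respiration, macrophage and leukocyte markers, endothelial markers, smooth muscle and pericyte markers, adipocyte markers, blood markers and circRNA biogenesis.

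Arrays with one scan identifier were taken as 1 slide. C57BL/6 replicates 1 and 2 lay on slide 1, while C57BL/6 replicate 3 shared slide 2 with all 3 db/db arrays. Group and slide are therefore partly confounded, and values with slide as a block rest on C57BL/6 replicate 3 as the only control array. Replicate numbers occur in both groups, and no label says what they mark. The alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, the percentile over probes detected on every array, the authors' table, other filters on dim probes, replicate and slide blocks, robust trended moderation, array weights, a plain test per probe and leaving out each array in turn. Normexp was run on the median spot intensity, because the files have no column of mean intensity. A fit to the slide 2 arrays alone was added after the data were examined.

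The test was checked on simulated arrays with the means and limma's moderated variances of the 14218 circRNA probes. Each run held 100 planted 2-fold and 100 planted 4-fold changes, and recovery after correction depends on how many are planted. In 5 runs it called 88.8% of 2-fold and 100% of 4-fold changes, with 13.8 false calls per run on average. These simulations held independent probes and no slide effect, so they describe the test and not these arrays.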

Results

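Circular RNAs of the cardiac apex were compared between db/db mice, which lack a working leptin receptor and become obese and diabetic, and C57BL/6 mice, with 3 animals per group at 21 weeks of age. The study's title places the comparison in cardiac fibrosis. Nearly every circRNA probe gave a signal, with 99.9% ± 0.051 well above background in C57BL/6 and 99.9% ± 0.12 in db/db (SD, n = 3, exact permutation p = 0.5). All 15 probes named as negative controls were also well above background on every array, so this mark does not establish that a circRNA was present. No spot was saturated. The 75th percentile of processed intensity was 715, 557 and 399 on C57BL/6 replicates 1, 2 and 3, and 494, 296 and 376 on db/db replicates 1, 2 and 3. On the log2 scale it averaged 9.08 ± 0.42 against 8.57 ± 0.37 (SD, n = 3, exact permutation p = 0.2), and the median background was 18.7 ± 1.2 against 19.2 ± 0.29 (SD, n = 3, exact permutation p = 0.6). By slide, the median background was 18 on both arrays of slide 1 and 19 to 20 on those of slide 2. Both arrays of slide 1, which are C57BL/6, also had a higher 75th percentile than every array of slide 2.

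The 10 spots of a repeated probe differed little within an array, with a median SD of 0.03 to 0.04 on the log2 scale. Between the arrays of a group the median SD of these repeated probes was larger, at 0.175 among C57BL/6 and 0.177 among db/db arrays. For circRNA probes it was 0.20 among C57BL/6 and 0.19 among db/db arrays. This spread can hold technical differences between arrays as well as differences between animals. Across circRNA probes, C57BL/6 replicate 3 correlated at 0.993 with both db/db replicate 3 and db/db replicate 1, and at 0.982 with db/db replicate 2, all on its own slide 2. Its correlation with C57BL/6 replicates 1 and 2, on slide 1, was 0.987 and 0.989. The correlations did not follow slide throughout. The 2 arrays of slide 1 correlated at 0.985, below the 0.988 of C57BL/6 replicate 2 with db/db replicate 1 on the other slide. Replicate 2 of db/db stood apart, at 0.971 to 0.982 with the other arrays. Probes are not independent replicates, so these coefficients describe the arrays only. The first principal component held 39.3% of the variance and the second 28.9%.

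**Figure D1:**
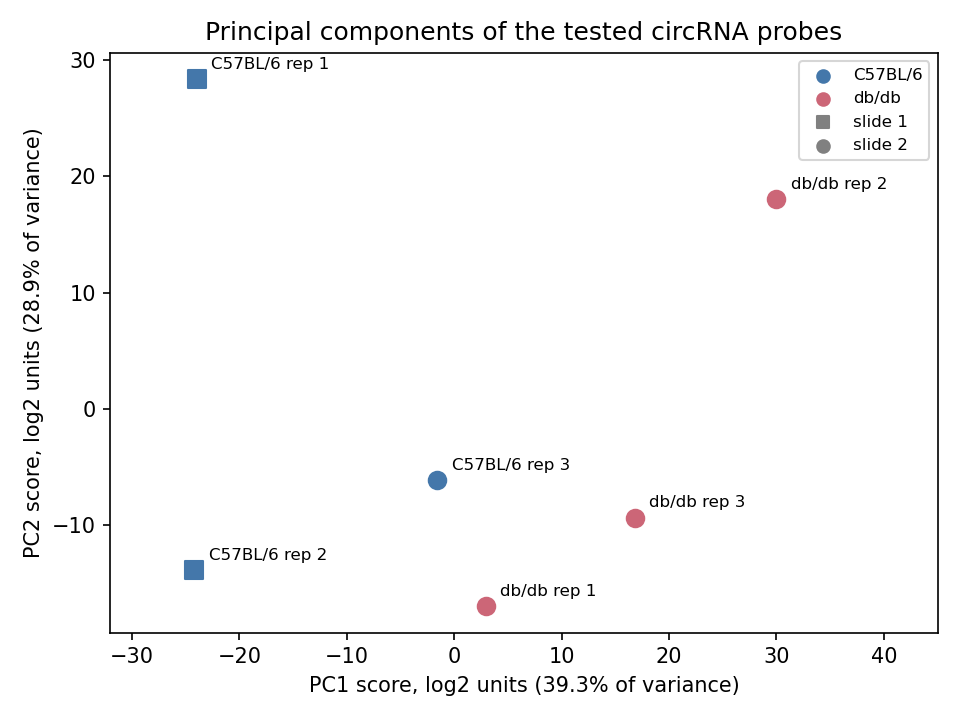
Scores of the 6 arrays on the first (39.3% of variance) and second (28.9%) principal components of the tested circRNA probes, in log2 units, with colour for group and shape for slide. C57BL/6 replicate 3, at -1.60 on the first component, lay closer to db/db replicate 1 (2.94) than to C57BL/6 replicates 1 and 2 (-23.97 and -24.19).

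The main question was which circRNAs differed in the db/db heart. The circRNA of probe ASCRP4009214 read 2.65-fold higher in db/db, with a log2 difference of 1.41 ± 0.24 (SE, n = 3 per group). ASCRP4005472 read 2.13-fold higher, with a log2 difference of 1.09 ± 0.19 (SE, n = 3 per group). In the other direction, ASCRP4013593 read 2.01-fold lower (log2 difference -1.004 ± 0.16, SE) and ASCRP4010416 read 2.03-fold lower (-1.02 ± 0.17, SE). With normexp these 2 differences were -0.66 and -0.77. Processed intensity was 46 to 185 for ASCRP4013593 and 124 to 542 for ASCRP4010416, below the negative-control probe MM9NEGATIVE016 (552 to 984) on every array. It was 466 to 1287 for ASCRP4009214, and 2748 to 5867 for ASCRP4005472, which lay above that probe on every array. For each of these 4 circRNAs all 3 db/db arrays lay on one side of all 3 C57BL/6 arrays, which the naming rule required.

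None of the 4 passed the correction, with a limma adjusted p of 0.221 for each. By limma, 0 of the 14218 tested circRNAs changed at an adjusted p under 0.05, while 1496 had an unadjusted p under 0.05, against 710.9 expected by chance. A plain test per probe on quantile-normalized values gave 0 after correction and 1547 before it. Of the 1496 circRNAs, 633 were higher and 863 lower in db/db, a share of 42.3% higher that became 58.9% (1064 higher, 743 lower) when arrays were centred on their medians. A fold of at least 1.5 left 626 circRNAs, 199 higher and 427 lower. The balance of these depended on scaling and arrays, with 289 higher and 346 lower under median centring, 275 and 276 without C57BL/6 replicate 2, and 102 and 465 without db/db replicate 2. The total was 1097 without C57BL/6 replicate 3 and 949 without db/db replicate 1.

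The groups did not overlap for 2409 circRNAs, or 16.9% of those tested, where chance gives 10%. The 12 circRNAs named as higher spanned 1.79-fold to 3.20-fold, and the 12 named as lower spanned 1.88-fold to 2.65-fold. With slide as a block, 185 circRNAs had an unadjusted p under 0.05 in place of 1496, and 0 passed the limma adjustment. Within slide 2 alone the number was 228, again with 0 after adjustment. The 4 circRNAs above kept their direction there, with log2 differences of 1.22 for ASCRP4009214, 0.71 for ASCRP4005472, -0.92 for ASCRP4013593 and -0.90 for ASCRP4010416, although the naming rule had already required them to differ from C57BL/6 replicate 3.

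**Figure D2:**
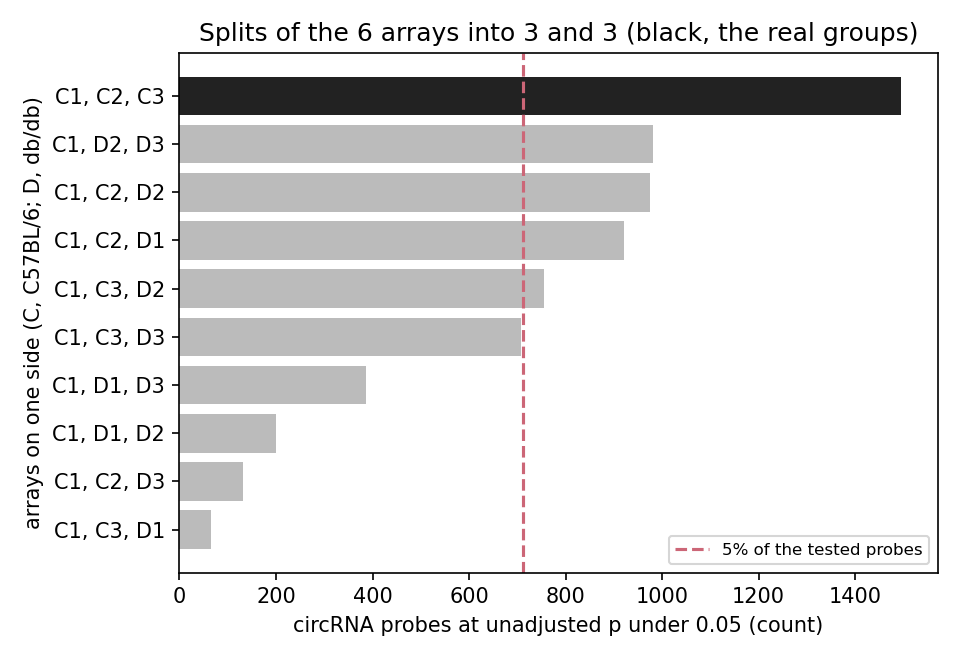
Number of circRNA probes at an unadjusted p under 0.05 (horizontal axis) for each of the 10 splits of the 6 arrays into 3 and 3, named by the arrays on one side (C, C57BL/6; D, db/db), with the real groups in black and a dashed line at 5% of the tested probes. The real split gave 1496 and the next highest 982.

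The number of circRNAs well above background on all 3 arrays of a group and on none of the other was 0, with no separate test. Requiring 2 of 3 arrays gave 2 circRNAs, both seen in C57BL/6 only. Because negative-control probes carried the same mark, these counts do not tell which circRNAs were expressed.

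The arrays also carried 50 probes for mRNAs, read here after the data were examined and on RNA depleted of linear transcripts. Gsta4, a glutathione transferase that clears products of lipid peroxidation, read 1.93-fold higher in db/db (log2 difference 0.95 ± 0.29, SE, n = 3 per group). Its level relative to the 75th percentile was 0.42 and 0.52 on db/db replicates 2 and 3, but -0.61 on db/db replicate 1, next to -0.60 on C57BL/6 replicate 3. Pex11a, a factor of peroxisome division, read 1.37-fold higher and E2f1, a cell-cycle transcription factor, also 1.37-fold higher. Anxa8, an annexin, read 1.31-fold higher, and for these 3 genes every db/db array lay above every C57BL/6 array. Of all 50 mRNA probes, 9 (18%) had groups that did not overlap, where chance gives 10%, among them Il2 with a log2 difference of only 0.13. The log2 difference of E2f1, 0.46, fell to 0.25 without C57BL/6 replicate 1 and to 0.17 with normexp. Ppara, the nuclear receptor that drives genes of fatty acid oxidation, read 1.71-fold lower (log2 difference -0.78 ± 0.27, SE, n = 3 per group), and its log2 difference was -0.41 with normexp. The processed intensity of Ppara was 140, 133 and 50 on C57BL/6 replicates 1, 2 and 3, and 70, 25 and 38 on the db/db arrays. That of E2f1 was 29.7 to 44.8 across arrays. Some negative-control probes read as bright, with 60 to 90 for MM9NEGATIVE008 and 62 to 126 for MM9NEGATIVE002. Others were brighter, up to 552 to 984 for MM9NEGATIVE016, or dimmer, down to 3.2 to 6.8 for MM9NEGATIVE012. The median circRNA signal of the arrays was 100 to 235, and on every array it lay below MM9NEGATIVE016.

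Of the list of fatty acid uptake and oxidation, 3 members had a probe, and all 3 read lower in db/db under every scaling run on them. Besides Ppara these were Acaa2, a mitochondrial thiolase of fatty acid oxidation, at -0.33 ± 0.15, and Cpt1a, an acyltransferase needed for fatty acid entry into mitochondria, at -0.13 ± 0.15 (log2 difference, SE). The direction of Cpt1a rested on small values, with -0.06 under normexp, -0.04 without db/db replicate 2 and 0.01 with array weights. The limma adjusted p was 0.265 for Ppara, 0.306 for Acaa2 and 0.674 for Cpt1a, and 0 of the 3 passed when adjusted over the list alone (smallest adjusted p 0.0537). From the list of inflammation and pyroptosis only Gsdmd, which forms the membrane pores of pyroptosis, had a probe. It read 1.29-fold higher, with every db/db array above every C57BL/6 array (log2 difference 0.37 ± 0.16, SE), with a limma adjusted p of 0.291 over all mRNA probes and 0.0463 adjusted over the list alone, where a single member leaves nothing to correct for. Its unadjusted p was 0.0665 with the replicate block, 0.549 with the slide block, 0.182 with array weights, and 0.0757 to 0.118 in the fits that left out 1 array other than C57BL/6 replicate 3. From the list of insulin signalling and glucose metabolism only Gpi1, phosphoglucose isomerase, had a probe, at -0.18 ± 0.15 (SE), with a limma adjusted p of 0.674 over all mRNA probes and 0.272 adjusted over the list alone, and its log2 difference was -0.10 without C57BL/6 replicate 1 and -0.07 with array weights.

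Among the other mRNAs, Actb, a cytoskeletal actin, differed by 0.18 ± 0.23, Hspb7, a heat shock protein of heart muscle, by -0.26 ± 0.16, and Apoe, a lipid carrier, by -0.04 ± 0.14 (log2 difference, SE). By limma, 0 of the 50 mRNA probes passed an adjusted p under 0.05, and 8 (16%) had an unadjusted p under 0.05, 7 higher and 1 lower. Of the 15 probes named as negative controls, 11 read higher in db/db, and 3 (20%), all higher, had such a p. Their log2 differences were 0.39, 0.44 and 0.67, beside 0.37 for Gsdmd and 0.46 for E2f1. A rise of this size was therefore not particular to mRNA probes. Among the 8 were 2 probes without a gene name, A_51_P213099 at 0.72 ± 0.27 and A_51_P237746 at 0.61 ± 0.20 (log2 difference, SE), which were 0.15 and 0.28 with slide as a block, and 0.42 and 0.40 without C57BL/6 replicate 1. Gsta4 alone passed without db/db replicate 1 (log2 difference 1.31, limma adjusted p 0.00319). The count of 8 became 4 without C57BL/6 replicate 1, 3 without C57BL/6 replicate 2 and 3 without db/db replicate 2.

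With slide as a block, 0 of the 50 mRNA probes had an unadjusted p under 0.05. The log2 differences were then 0.71 for Gsta4, 0.34 for Pex11a, 0.21 for E2f1, 0.23 for Anxa8, 0.14 for Gsdmd and -0.26 for Ppara. Those of Acaa2 and Cpt1a were -0.25 and 0.00. All 50 mRNA probes were well above background on every array, including those of Lhx1, a developmental transcription factor, and Olfr1307, an olfactory receptor, so a detected signal does not by itself establish a transcript.

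**Figure D3:**
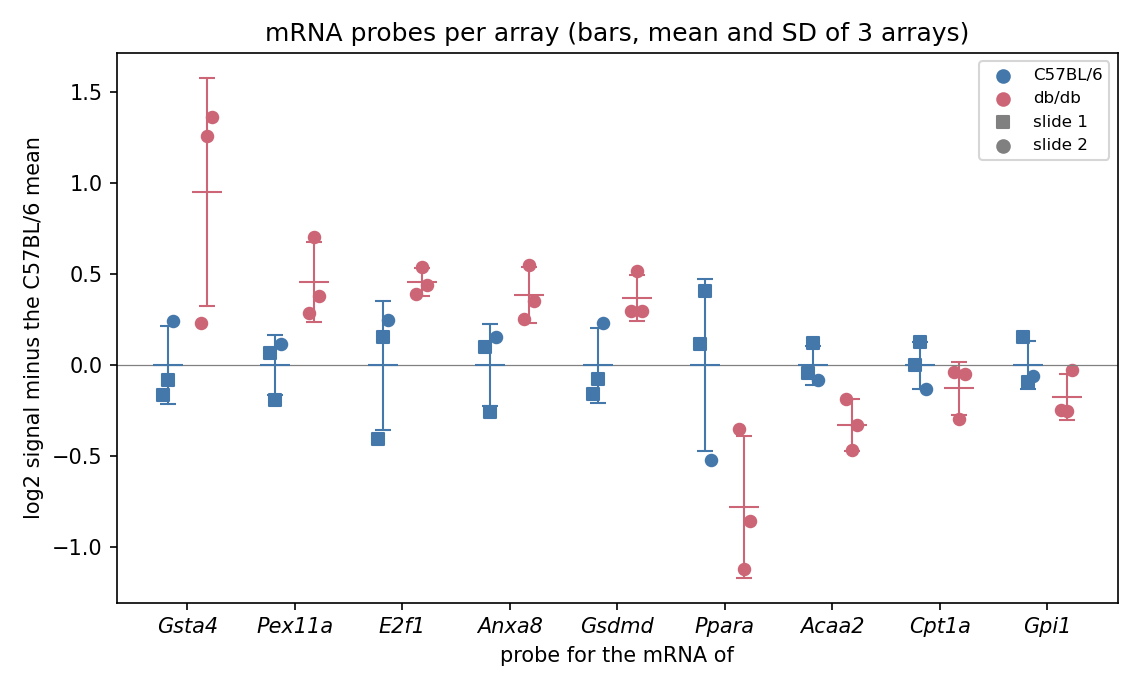
Log2 signal of mRNA probes on each array (vertical axis, minus the C57BL/6 mean) for the genes on the horizontal axis, with colour for group, shape for slide, and bars for the mean and SD of 3 arrays. For Gsta4, db/db replicate 1 lay level with C57BL/6 replicate 3, and for Ppara, C57BL/6 replicate 3 lay among the db/db arrays.

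The 14 probes named as circRNA controls were read in the same way after the data were examined. In db/db, 13 of the 14 read lower, with a median log2 difference of -0.27 that was -0.15 with normexp, and the direction was the same under every scaling run on them. Their median relative to the 75th percentile was -0.84, -0.68 and -1.34 on C57BL/6 replicates 1, 2 and 3, and -1.35, -1.28 and -1.74 on db/db replicates 1, 2 and 3. By limma 0 passed an adjusted p under 0.05 (smallest 0.0574), and 5 had an unadjusted p under 0.05. Within slide 2 the median difference was -0.10, with 10 of the 14 lower.

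**Figure D4:**
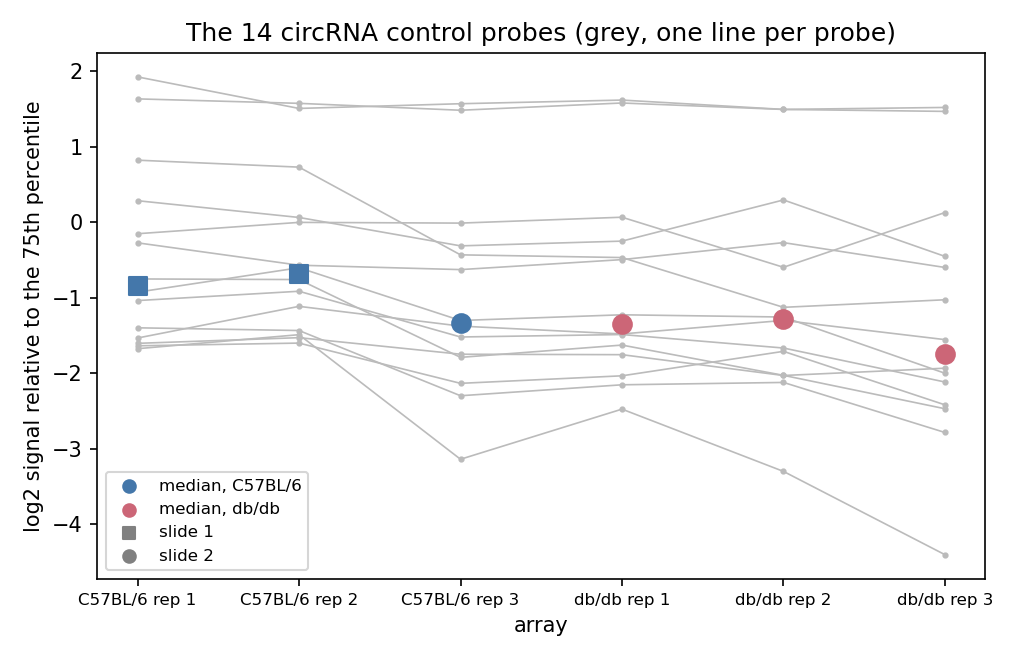
Log2 signal of the 14 circRNA control probes relative to each array's 75th percentile (vertical axis) on the 6 arrays (horizontal axis), with a grey line per probe and a large symbol for the median, coloured by group and shaped by slide. The median was -0.84 and -0.68 on slide 1, and between -1.74 and -1.28 on slide 2.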

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

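The tests of chance, slide and linear RNA for circRNAs, and all tests of the mRNA and control probes, were chosen after the results were seen, while the test of dim probes was written before and the reading of its result was widened afterwards. Among the 44 repeated probes outside the circRNA and mRNA comparisons, 3 read higher on every db/db array than on every C57BL/6 array, and 6 read lower on every db/db array, where chance gives 2.2 each way. All 3 higher probes are named as negative controls, and so is 1 of the lower probes, MM9NEGATIVE010 (log2 difference -0.15). The log2 difference was 0.393 for MM9NEGATIVE017, 0.443 for MM9NEGATIVE016 and 0.349 for MM9NEGATIVE008, and within slide 2 it was 0.22, 0.31 and 0.09. Of the 15 probes with such names, 11 read higher in db/db. Their median log2 difference was 0.12, but it was 0.01 with normexp and 0.006 within slide 2. The largest rises, 0.73 for MM9NEGATIVE003 and 0.67 for MM9NEGATIVE002, came with groups that overlapped. All 15 probes with such names were well above background on all 6 arrays.

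The number of circRNAs at an unadjusted p under 0.05, 1496, was reached by 1 of the 10 splits of the 6 arrays, the real one, and the highest other split gave 982, but 10 splits are too few for a share under 0.05. Noise of dim probes as the whole cause is argued against by the brightest 3555 circRNAs, of which 9.25% had such a p, beside 9.70% of the dimmest. This is a thin reading, since 9.25% missed the 10% set beforehand for excluding the cause, the rule used is the third tried for this value and was adopted after it was seen, and it rests on the share staying above the 6% set beforehand for the cause in its binomial lower bound (8.32%, too high where probes move together) and with 1 array left out (6.30% to 9.96%), although the dimmest share exceeded the brightest without C57BL/6 replicate 3 (14.2%) and without db/db replicate 2 (8.35%). A slide difference stays open, since parting the 2 arrays of slide 1 from the other 4 gave 2024 circRNAs, but parting C57BL/6 replicate 1 and db/db replicate 2 from the rest gave 2035, and among circRNAs picked without C57BL/6 replicate 3 that array lay at a median position of 0.616 between the other C57BL/6 arrays (0) and db/db (1), where the same position was 0.209 for C57BL/6 replicate 1 and 0.204 for C57BL/6 replicate 2. Uneven removal of linear RNA was not decided, with a median shift of the 50 mRNA probes of -0.586 SD of the per-array medians. On the log2 scale this shift was small, at -0.027, and it was 0.020 under median centring, so its sign depended on scaling. The genotype of the mice remains an untested biological explanation.

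For the mRNA probes, 8 of 50 had an unadjusted p under 0.05, a count reached by 1 of the 10 splits, the real one, with 3 in the highest other split, and again 10 splits are too few for a share under 0.05. The median ratio of the difference within slide 2 to the pooled one was 0.455, but the 8 were picked by the pooled p, which shares these arrays and favours large pooled differences, so neither the signs nor a ratio below 1 decide. A slide difference could account for part of the values of Gsta4, Ppara and the others, and slide and group are told apart only weakly with 1 C57BL/6 array on slide 2 (Gsta4 0.71, p 0.126, with slide as a block). A difference between db/db and C57BL/6 hearts stays open as well.

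The lower signal of the 14 circRNA control probes in db/db is consistent with a slide difference. Their median on C57BL/6 replicate 3 was -1.338, inside the range of the db/db arrays on the same slide and below both arrays of slide 1. This rests on 1 array, and a smaller difference between the groups within slide 2 was not excluded.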

How the results depend on the processing

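All mRNA alternatives and the fit to slide 2 alone were chosen after the results were seen, as were the median intensity for normexp and the shares per signal class with 1 array left out; the others were planned. The count of 0 circRNAs by limma at an adjusted p under 0.05 was the same in every alternative run, with the smallest adjusted p between 0.0619 and 0.99992, beside 1496 at an unadjusted p under 0.05 and 0 after correction by the plain test. The 1496 became 185 with the slide block and 228 in slide 2 alone, where the contrast rests on 1 C57BL/6 array and both counts lie below the 710.9 expected by chance, so they say little about a slide effect, and 1021 to 1850 with 1 array left out. The 626 with a fold of at least 1.5 became 276 with normexp, 410 in the authors' table, 163 with the slide block, 170 in slide 2 alone and 320 (113 higher, 207 lower) by the plain test. Their share that was higher, 31.8%, was 45.5% with median centring and 18.0% to 49.9% with 1 array left out. Leaving out 1 array gave 477 to 1097, the highest without C57BL/6 replicate 3, and 949 without db/db replicate 1; the cause was not tested. The share of the 1496 that was higher, 42.3%, was 58.9% with median centring and 33.2% with array weights, and 28.0% to 53.1% with 1 array left out. The 8 mRNA probes at an unadjusted p under 0.05 became 0 with the slide block, 0 in slide 2 alone and 5 with array weights. With 1 array left out they numbered 3 to 8, namely 4 without C57BL/6 replicate 1, 3 without C57BL/6 replicate 2 and 3 without db/db replicate 2. The count of mRNA probes past the limma adjustment ranged from 0 to 1 in those fits, the 1 being Gsta4 without db/db replicate 1 (adjusted p 0.00319, where the smallest mRNA adjusted p of the alternatives lay between 0.00319 and 0.962). Detection in one group only gave 2 circRNAs when 2 of 3 arrays sufficed. Correlations of deviations were -0.26, -0.14 and 0.42 for the 3 replicate numbers, too few and too mixed to tell whether the numbers pair the arrays. The replicate block gave 1587 circRNAs at an unadjusted p under 0.05 and 0 after adjustment. Its smallest limma adjusted p was 0.136, beside 0.221 in the main fit. For the 4 circRNAs given by probe ID, all 72 alternative values kept their direction. Their choice by p on these arrays favoured this, and several settings share an estimate. Of the values for named or listed mRNA probes, 140 stayed on the same side of an unadjusted p of 0.05. Another 44 rose above it, 3 fell below it and none turned a difference with a p under 0.05 around. Sizes moved too, with log2 differences under normexp of -0.66 for ASCRP4013593, -0.41 for Ppara, 0.17 for E2f1 and 0.30 for A_51_P213099. Host gene lists, circRNA classes and earlier-studied circRNAs were not run, since probes could not be matched to them. Signal over background set little limit, as 3 circRNA probes were dropped as dim.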

Other observations

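The balance of higher and lower circRNAs differed between classes of signal, a pattern noticed and examined only after the data were seen. The tested circRNAs were ranked by mean signal and divided into 4 classes of equal size. Among the brightest 3555, 222 circRNAs with an unadjusted p under 0.05 were higher in db/db and 107 lower. The next class had 136 higher and 269 lower, the one below it 121 higher and 296 lower, and the dimmest 154 higher and 191 lower. The median log2 difference of all circRNAs was 0.04 in the brightest and in the dimmest class, and -0.01 in both between. Higher circRNAs outnumbered lower ones in the brightest class under all 6 scalings, with 200 against 149 after quantile normalization of the processed intensities and 257 against 167 in the authors' table. In the class with 121 higher and 296 lower, lower circRNAs outnumbered higher ones under all 6. In the class with 136 higher and 269 lower, normexp turned the balance to 284 higher against 276 lower. In the dimmest class, median centring turned it to 304 higher against 170 lower. None of these circRNAs passed the limma adjustment in any scaling, and the balance was not examined within slide 2.

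Mbp, a myelin protein, and Prdx2, a peroxidase abundant in red cells, differed by 0.10 ± 0.31 and 0.03 ± 0.14 between db/db and C57BL/6 (log2 difference, SE). The signal of Mbp varied widely between arrays, with an SD of 0.56 among C57BL/6 and 0.47 among db/db arrays.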
